A study of Mus musculus with 24 samples.

How the data were processed

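RNA of Olig2-positive cells was measured on 24 Illumina arrays with a biotin label and TotalPrep amplification, per the labels: 4 arrays for each of total RNA and ribosome-bound RNA in normal brain, PDGF glioma and PTEN-deleted glioma. The deposited signal table held probe intensity without normalization for 25697 probes, with a detection p-value per probe and array, per the file headers. Between 23.2% and 29.2% of the probes of an array were below 0, so a background had been subtracted, although the files do not say so. The authors also deposited log2 values for 9653 probes, quantile normalized over the arrays (median 8.89 on each). Their order within each array was that of the signal (Spearman 1). Partek is named, with no role or version, per the submitters' processing notes. The 9653 probes were those with a detection p under 0.05 on all 20 arrays other than normal brain total RNA, and only this table gives gene names. Genes below background in any glioma array or in the ribosome-bound RNA of normal brain therefore have no name here, which includes genes lost in the gliomas. Normal brain total RNA was exempt, so naming favours genes that rise from it over genes that fall. The lists lost members in this way: 10 of 22 mitosis, 8 of 21 interferon and 3 of 16 neuron names were measured. Of its probes 9130 were matched to 6971 current gene names, 9126 of them through a gene identifier, 4 were not found in the reference gene table and 0 matched several genes. The other 523 probes of that table and the rest of the signal table were tested as unnamed probes. No genome build is named in the files, so no positions are given.

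The signal was background corrected with the limma function nec, which reads the background from the detection p-values, with an offset of 16, then quantile normalized over the 24 arrays and put on the log2 scale (R 4.3.3, limma 3.58.1). Probes with detection p under 0.05 on at least 4 arrays of a fit were kept. Each named gene was represented by its probe with the highest mean. Of the named genes 1658 had several probes, and oppositely called probes of the same gene numbered from 0 to 88 genes per comparison. Linear models were fitted with lmFit and eBayes (trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are log2 with their standard error. A gene with a detection p of 0.05 or more on all 4 arrays of a group was called not above background there, and its fold is given as a lower bound, computed against the lowest detected level.

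Tissues were compared within a fraction, over its 12 arrays, with no block. Fractions were compared over all 24 arrays with the tissue sample as the replicate block, since the labels say that each tissue sample was divided equally into paired datasets. The change of the ribosome-minus-total difference between tissues was a contrast in this model. The pairing was checked on the values: after removal of group means, both arrays of a tissue sample correlated with r from 0.07 to 0.59, and each was the best match of its partner in 11 of 12 cases. Replicate numbers did not pair arrays across tissues (r from -0.13 to 0.44 in total RNA, with 2 of 12 best matches, and -0.04 to 0.43 in ribosome-bound RNA, with 4 of 12). The labels do not say that replicates are separate animals, so p-values measure the spread between these samples. The fractions differ in isolation as well as in ribosome binding, papain dissociation and sorting against homogenisation and immunoprecipitation, and no comparison separates these.

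The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Genes named are the 10 largest rises and 10 largest falls of a comparison among called genes with complete separation of the samples, up to 4 called members of each list in its majority direction and 2 in the other, and Pten, Pdgfra, Olig2, Pdgfb, Cdkn2a, Trp53, Egfr and Mki67. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. No list passed with the estimated correlation in any comparison. The tested lists were oligodendrocyte progenitor, mature oligodendrocyte and myelin, neuron and astrocyte markers, immediate early and dissociation response, replication, mitosis, homologous recombination, ribosomal protein, other terminal oligopyrimidine, translation initiation factor, oxidative phosphorylation, FOXO target, cholesterol and fatty acid synthesis, hypoxia and glycolysis, interferon, matrix and mesenchymal, neural progenitor, p53 target and unfolded protein response genes. Lists with fewer than 3 measured members were not tested: microglia, endothelial, choroid plexus, erythrocyte and nuclear noncoding RNA. A list of sex-linked genes was not tested.

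The fits were tested on simulated data with 50 changed genes at each fold. A fold of 4 was called in 98% to 100% of cases over the 12 comparisons, a fold of 2 in 76% to 100%, a fold of 1.5 in 10% to 54% and a fold of 1.25 in 0% to 14%, among 11619 to 13145 genes and unnamed probes. No call had the wrong direction, and 3 to 12 unchanged genes were called. A list of 12 genes shifted by 0.5 was called in each comparison with both correlations, and no other list was. The simulated genes varied independently, few were changed and their values were drawn after normalization. This therefore does not show how often a list of correlated genes is called falsely in the real data. Alternatives were no background correction (values raised to 1), an offset of 50, scaling of arrays to an equal median, fractions normalized separately, the authors' values, no filter, a stricter filter (detection p under 0.01 on all 4 arrays of a group), the mean of a gene's probes, array quality weights, other blocks, and each replicate left out in turn. Other sample splits and further tests on gene length (genomic length from the reference table, 100 nearest genes) are in the closing section. Intervals resampled list genes, not tissue samples. The splits with group means removed, which give the correlation between the fractions expected with no tissue difference, were added after the data were seen. Figures used matplotlib 3.10.9 and Python 3.11.15.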

Results

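RNA from Olig2-positive cells was measured on 24 Illumina expression arrays. Olig2 is a transcription factor of the oligodendrocyte lineage. The cells came from 3 mouse tissues: normal brain, a PDGF glioma and a PDGF glioma with PTEN deleted, called PTEN-deleted glioma here. PDGF is a growth factor that drives the division of oligodendrocyte progenitor cells, and PTEN is a phosphatase that opposes PI3K signalling. Each tissue gave 2 fractions. Total RNA came from GFP-positive cells sorted after papain dissociation, and ribosome-bound RNA was pulled down with an antibody against GFP after mechanical homogenisation. Each of the 6 groups held 4 arrays, and each of the 12 tissue samples was divided equally between the fractions, so that the fractions were paired within a tissue sample. The series title asks how the regulation of translation differs in these tumours.

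Between 11539 and 13581 of the 25697 probes were above background (detection p under 0.05) on an array, and the number of arrays, 4 per group, limited the precision. The median signal per array before normalization was 13.8 to 15.3 in normal brain total RNA and 16.2 to 18.8 in its ribosome-bound RNA. It was 32.6 to 52.3 and 25.9 to 45 in PDGF glioma, and 11.6 to 14.8 and 9.6 to 11.2 in PTEN-deleted glioma, in the same order. Array brightness thus differed by tissue without overlap, and is confounded with it, in every comparison between tissues except that of PTEN-deleted glioma with normal brain in total RNA. The first principal component held 49.1% of the variance and set normal brain apart from both gliomas. The second held 26% and set the fractions apart. Arrays of the same group correlated across probes with r from 0.97 to 0.996, where probes are not independent replicates.

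**Figure D1:**
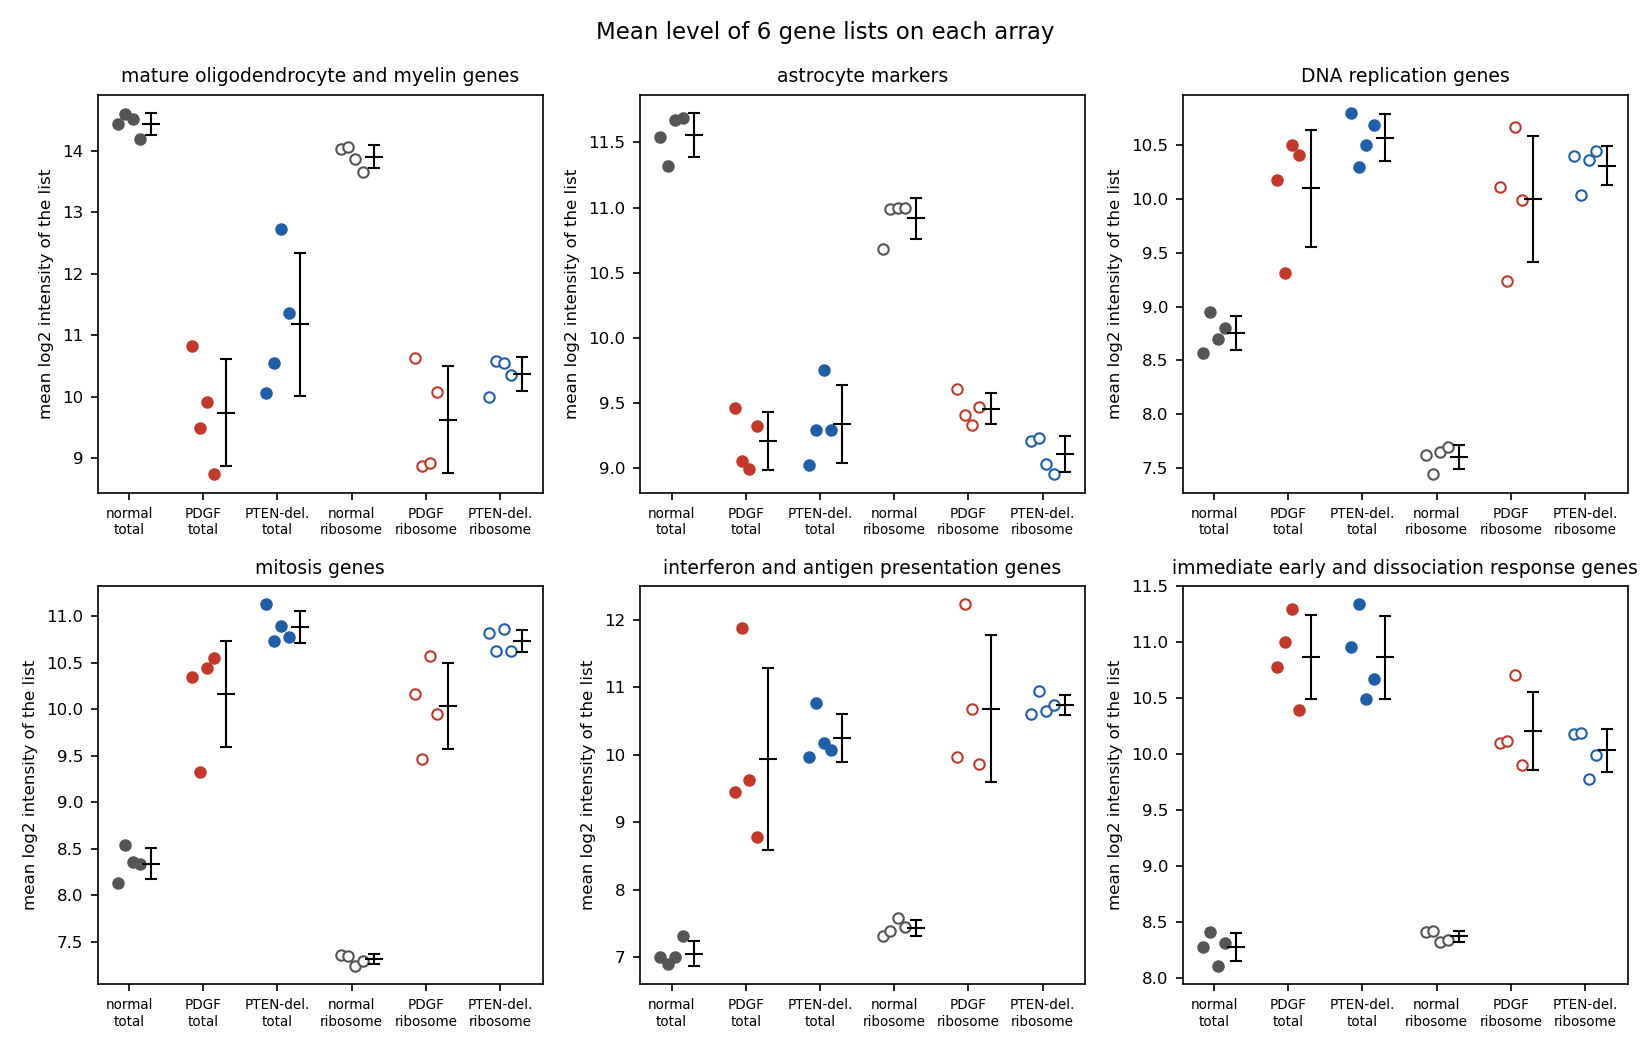
Mean log2 intensity of 6 gene lists on each of the 24 arrays, by tissue and fraction; filled points are total RNA, open points ribosome-bound RNA, and bars are the mean ± SD of 4 arrays. Mitosis genes lay between 8.13 and 8.54 in normal brain total RNA and between 9.32 and 11.13 in total RNA of both gliomas, with PDGF glioma replicate 2 the lowest of these.

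Pten, the targeted gene, could not be reported, since none of its probes could be matched to a gene name. Pdgfb, Cdkn2a, Trp53 and Mki67 were not analysed here for the same reason. Pdgfra, the receptor for PDGF and a marker of oligodendrocyte progenitors (probe ILMN_1235932), had a total RNA level of 12.11 ± 0.63 log2 units in normal brain (mean ± SD, n = 4). It was 14.55 ± 0.08 in PDGF glioma and 13.99 ± 0.08 in PTEN-deleted glioma. In ribosome-bound RNA its levels were 11.74 ± 0.23, 12.84 ± 0.27 and 11.81 ± 0.32 in the same order. Olig2 (probe ILMN_2724709) rose in total RNA, from 6.79 ± 0.17 in normal brain to 8.47 ± 0.44 in PDGF glioma and 8.16 ± 0.54 in PTEN-deleted glioma. Its ribosome-bound levels were 8.58 ± 0.07, 8.64 ± 0.49 and 8.48 ± 0.14, and neither glioma differed from normal brain beyond the threshold (adjusted p = 0.79 and 0.69). Egfr, an epidermal growth factor receptor (probe ILMN_3128725), moved in opposite directions in the fractions. Its total RNA level fell from 7.65 ± 0.16 in normal brain to 6 ± 0.25 in PDGF glioma and 6.1 ± 0.25 in PTEN-deleted glioma, while its ribosome-bound level rose from 5.41 ± 0.13 to 6.07 ± 0.46 and 7.08 ± 0.36. The rise in ribosome-bound RNA of PDGF glioma was not called with the authors' values (adjusted p = 0.061) or without PDGF glioma replicate 1 (0.071).

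In total RNA, PDGF glioma had much lower levels of myelin and astrocyte genes than normal brain and higher levels of cell cycle, immediate early and interferon genes. All 9 measured mature oligodendrocyte and myelin genes fell, with a median log2 difference of -4.26. Each was counted by its probe with the highest mean, and Mbp also had a probe called higher, here and in both fractions of each glioma against normal brain. The differences were -7.69 ± 0.51 for Opalin and -6.83 ± 0.76 for Mog, membrane proteins of myelin, and -5.85 ± 0.86 for Mobp (± standard error, n = 4 arrays per tissue). Of 7 astrocyte markers, 6 fell and 1 rose (median -1.94). Gja1, the gap junction protein connexin 43, changed by -7.14 ± 0.51 and the glutamate transporter Slc1a2 by -3.61 ± 0.19, while Gfap, an intermediate filament above background on 3 of 4 normal arrays, rose by 1.22 ± 0.32. The camera test gave the myelin list an adjusted p of 6.7e-05 and the astrocyte list 0.0064. With an estimated correlation the adjusted p was 0.41 and 0.25.

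The cell cycle lists rose as a whole in PDGF glioma total RNA. All 13 DNA replication genes rose (median 1.28), among them Mcm6, part of the replicative helicase, by 1.95 ± 0.19 and Rrm2, of deoxynucleotide synthesis, by 1.72 ± 0.22. All 10 mitosis genes rose (median 1.94), with Tpx2 at 2.39 ± 0.24 and the kinase Cdk1 at 2.02 ± 0.24. Of the 11 immediate early and dissociation response genes 7 rose and none fell (median 3.19), with Fos at 4.91 ± 0.26 and Socs3 at 4.22 ± 0.35. Of 8 interferon and antigen presentation genes 7 rose (median 2.80), with Usp18 at 3.89 ± 0.55 and Ifitm3 at 2.92 ± 0.53. Among all 6971 named genes 2780 rose and 2008 fell in this comparison, and genes lost in the gliomas had no name. Adjusted p by camera was 0.0027 for replication, 0.0016 for mitosis, 0.0017 for the immediate early list and 0.018 for the interferon list. With an estimated correlation it was 0.43, 0.43, 0.41 and 0.43, and with arrays scaled only to an equal median the interferon call ended (adjusted p = 0.17). PDGF glioma replicate 2 had a mean mitosis level of 9.32 in total RNA, far from the 10.35 to 10.55 of the other replicates, and the highest mean interferon level, 11.88 against 8.78 to 9.62.

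Ribosomal protein genes and other terminal oligopyrimidine mRNAs also rose, while the list of translation initiation factors did not pass (12 of 23 rose and 5 fell, camera adjusted p = 0.11). Of 54 cytosolic ribosomal protein genes 51 rose, or 52 adjusted over the list alone, and none fell (median 0.88). Rplp0 rose by 1.95 ± 0.21 and Rpl12 by 1.56 ± 0.09. Of 12 other mRNAs with a terminal oligopyrimidine tract, the motif through which mTOR signalling controls translation, 11 rose (median 1.03), with the poly(A)-binding protein Pabpc1 at 2.59 ± 0.16. By camera, the adjusted p was 1.7e-11 and 0.0013, and with an estimated correlation the adjusted p was 0.41 and 0.25. FOXO target genes, which PI3K signalling represses, went the other way: 7 of 9 fell, or 8 adjusted over the list alone, and 1 rose (median -1.09). The ubiquitin ligase gene Fbxo32 changed by -2.96 ± 0.26 and Pik3ip1, an inhibitor of PI3K, by -2.37 ± 0.27. Of 15 cholesterol and fatty acid synthesis genes 11 fell and 1 rose (median -1.02), with Msmo1 at -2.42 ± 0.21. These lists had camera adjusted p of 0.005 and 0.0013, and 0.41 for both lists with an estimated correlation.

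Of 10 extracellular matrix and mesenchymal genes, 7 rose and 1 fell (median 2.02). Tnc, the matrix protein tenascin C, rose by 4.18 ± 0.38 and the intermediate filament Vim by 3.86 ± 0.29, while Sparc changed by -2.78 ± 0.31. In the camera test the adjusted p was 0.044, and 0.43 with an estimated correlation. The call ended with median scaling (adjusted p = 0.23), with an offset of 50 (0.052), with array weights (0.056), without PDGF glioma replicate 2 (0.057) and without normal brain replicate 2 (0.055). Of 12 oligodendrocyte progenitor markers 8 rose and 2 fell (median 1.13, camera adjusted p = 0.1, and 0.042 without normal brain replicate 1). Cspg4, the NG2 proteoglycan, rose by 2.24 ± 0.29 and Bcan, a brain proteoglycan, changed by -1.10 ± 0.14. All 3 neuron markers rose (median 1.34, camera adjusted p = 0.11), with Syn1 at 1.87 ± 0.17. Of 12 p53 target genes 9 rose and 2 fell (median 0.69, camera adjusted p = 0.1), with the cell cycle inhibitor Cdkn1a at 2.83 ± 0.20. Of 13 hypoxia and glycolysis genes 9 rose and 2 fell (median 1.14, camera adjusted p = 0.058). This list passed with the authors' values (0.03) and without PDGF glioma replicate 1 (0.047) or 3 (0.045) or normal brain replicate 4 (0.048). Ldha, of lactate synthesis, rose by 2.65 ± 0.14 and Ndrg1 changed by -5.40 ± 0.36.

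Among single genes, the rises with the largest fitted values included 3 that were not above background on any of the 4 normal arrays. Vgf, a neuropeptide precursor, was at least 141-fold higher, Moxd1 at least 128-fold and Rflna at least 40.6-fold. The tubulin gene Tubb6 rose by 6.56 ± 0.15, the kinase anchor gene Akap12 by 6.08 ± 0.16, the collagen gene Col18a1 by 6.03 ± 0.24 and the growth cone protein gene Gap43 by 5.84 ± 0.19 (each adjusted p at or below 5.1e-11). Ptgds, of prostaglandin D2 synthesis, changed by -7.03 ± 0.59, the carbonic anhydrase gene Car2 by -6.68 ± 0.46 and the claudin gene Cldn10 by -6.42 ± 0.43. In each of these genes every array of PDGF glioma lay on the same side of every normal array. In limma, 7985 of the 12212 genes and unnamed probes tested passed an adjusted p of 0.05, with 4367 higher and 3618 lower in PDGF glioma. The share that was higher was 54.7%, and 72.8% with median scaling, which moved the median of all genes from 0.09 to 0.45. Except where stated, counts of list members adjusted over the list alone were the same as those over all genes in this comparison.

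PTEN-deleted glioma also had lower myelin and astrocyte levels than normal brain in total RNA and higher cell cycle and immediate early levels. All 9 myelin genes fell (median -3.21), with Opalin at -5.18 ± 0.51 and Cnp, an enzyme of myelin, at -3.46 ± 0.36. Of 7 astrocyte markers 6 fell (median -1.73), with Gja1 at -5.61 ± 0.51 and Slc1a2 at -3.26 ± 0.19. Of 13 replication genes 12 rose (median 1.94), with Rrm2 at 2.88 ± 0.22, and all 10 mitosis genes rose (median 2.48), with the kinase Plk1 at 3.27 ± 0.21 and Cdc20, of the anaphase promoting complex, at 2.78 ± 0.22. Of 11 immediate early genes 9 rose and 1 fell (median 3.00), with Socs3 at 4.75 ± 0.35 and Fos at 4.40 ± 0.26. As lists, their camera adjusted p was 0.00043 for myelin, 0.0038 for astrocyte, 0.00043 for replication, 0.00021 for mitosis and 0.002 for the immediate early list. With an estimated correlation the adjusted p was 0.28 for the astrocyte list and 0.42 for each of the others.

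Of 54 ribosomal protein genes 52 rose and none fell in PTEN-deleted glioma (median 0.89), with Rplp0 at 2.21 ± 0.21 and Rpl29 at 1.59 ± 0.11. Of 12 other terminal oligopyrimidine mRNAs 10 rose (median 0.83), with Pabpc1 at 2.02 ± 0.16. Of 9 FOXO target genes 7 fell and 1 rose (median -1.52), with Pik3ip1 at -3.39 ± 0.27 and Txnip, an inhibitor of glucose uptake, at -2.74 ± 0.27. Of 15 cholesterol and fatty acid synthesis genes 7 fell and 1 rose (median -0.45), with Dhcr7, the last enzyme of cholesterol synthesis, at -1.63 ± 0.17. The camera adjusted p was 9.4e-12, 0.002, 0.0017 and 0.029 in this order, and with an estimated correlation the adjusted p was 0.42, 0.28, 0.28 and 0.43.

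Hypoxia and glycolysis genes, interferon genes, matrix genes and p53 target genes also rose in PTEN-deleted glioma. Of 13 hypoxia and glycolysis genes 9 rose and 1 fell (median 1.11), with the hexokinase gene Hk2 at 4.07 ± 0.31 and Egln3, an oxygen sensor, at 2.99 ± 0.27. Of 8 interferon genes 7 rose (median 3.38), with Isg15 at 3.68 ± 0.51. Of 10 matrix and mesenchymal genes 9 rose and 1 fell (median 2.16), with Vim at 4.21 ± 0.29 and Sparc at -3.51 ± 0.31. Of 12 p53 target genes 9 rose and 2 fell (median 1.25), with Cdkn1a at 3.46 ± 0.20. Adjusted p by camera was 0.027, 0.01, 0.021 and 0.029 in this order. With an estimated correlation the adjusted p was 0.43 for hypoxia and 0.42 for the others. Of 12 oligodendrocyte progenitor markers 8 rose and 1 fell (median 0.77, camera adjusted p = 0.099, and 0.03 without normal brain replicate 1), with Cacng4 at 3.10 ± 0.20.

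Single genes again showed large differences from normal brain. Moxd1 was at least 206-fold, Rflna at least 33.1-fold and Vgf at least 29.1-fold higher, since none of the 4 normal arrays was above background for them. Tubb6 rose by 6.43 ± 0.15, Col18a1 by 5.70 ± 0.24 and Rasl11a by 5.31 ± 0.16. The membrane receptor gene Paqr7 changed by -6.15 ± 0.22, the amino acid transporter gene Slc7a10 by -5.99 ± 0.42 and Lrig1, which restrains growth factor receptors, by -4.97 ± 0.20. All arrays of the groups were separated in each, and each adjusted p was at or below 1.9e-08. In total 7642 of 12212 passed, 4055 higher and 3587 lower. Counts of these list members adjusted over the list alone did not differ.

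The gliomas share their normal brain controls, so their overlap was measured against that expected from random spread in shared controls. Of 12212 genes, 3393 rose and 2964 fell in both gliomas, and 68 were called in opposite directions. Calls made independently of each other would give 1450 and 1063. The log2 differences of both comparisons correlated across genes with r = 0.95 and a covariance of 1.67, while simulated data with shared controls and no tissue difference gave r = 0.5, a covariance of 0.02 and 0 shared calls (20 simulations). With the 4 normal arrays split between the comparisons, in 6 ways, 5118 to 5328 calls were shared and r was 0.92 to 0.94. Genes are not independent replicates in these correlations.

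In ribosome-bound RNA, PDGF glioma again had lower myelin and astrocyte levels than normal brain and higher cell cycle, interferon, ribosomal protein and terminal oligopyrimidine mRNA levels. All 9 myelin genes fell (median -4.49), with Opalin at -6.37 ± 0.34 and Mag, a myelin adhesion protein, at -5.14 ± 0.41. Of 7 astrocyte markers 5 fell and 1 rose (median -1.30), with Gja1 at -5.12 ± 0.22 and Slc1a3 at -1.72 ± 0.13. All 13 replication genes rose (median 2.32), with Rrm2 at 3.64 ± 0.28 and Pcna, the sliding clamp of DNA polymerase, at 3.25 ± 0.27. All 10 mitosis genes rose (median 2.72), with Nusap1 at 3.32 ± 0.20 and Top2a at 3.26 ± 0.23. By camera, the adjusted p was 2.9e-06, 0.013, 6e-06 and 6e-06 in this order, and with an estimated correlation the adjusted p was 0.31, 0.31, 0.39 and 0.34. PDGF glioma replicate 2 had a mean mitosis level of 9.46, against 9.95 to 10.57 in the other replicates, and a mean interferon level of 12.23, against 9.86 to 10.68.

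Of 11 immediate early genes 7 rose in the ribosome-bound RNA of PDGF glioma (median 2.52), with Fos at 4.59 ± 0.20 and Egr1 at 2.80 ± 0.15. Among 54 ribosomal protein genes 38 rose, or 39 adjusted over the list alone, and 1 fell (median 0.53), with Rplp0 at 2.14 ± 0.15 and Rpl41 at -0.32 ± 0.08, which became 0 with median scaling (adjusted p = 0.99). Of 12 other terminal oligopyrimidine mRNAs 11 rose (median 1.50), with the elongation factor gene Eef2 at 1.66 ± 0.24. Of 8 interferon genes 7 rose (median 3.68), with Psmb9, of the immunoproteasome, at 4.53 ± 0.45. Of 10 matrix and mesenchymal genes 7 rose and 1 fell (median 1.82), with Vim at 3.83 ± 0.20. These lists had camera adjusted p of 0.0047, 1e-05, 8.4e-05, 0.0014 and 0.018 in this order. With an estimated correlation the adjusted p was 0.39, 0.34, 0.34, 0.40 and 0.40, and the matrix call ended with median scaling (adjusted p = 0.085). Of 3 neuron markers 2 fell and 1 rose (median -0.93, camera adjusted p = 0.19), and of 12 oligodendrocyte progenitor markers 3 rose and 3 fell (median -0.02, camera adjusted p = 0.55), with Gpr17 at -2.53 ± 0.21.

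Among single genes, Tubb6 rose by 6.12 ± 0.14, Rflna by 5.27 ± 0.19, the cell cycle inhibitor gene Cdkn2b by 4.73 ± 0.17, the protease inhibitor gene Serpina3n by 4.60 ± 0.29 and the cyclin gene Ccnd2 by 4.02 ± 0.18. Car2 changed by -5.55 ± 0.38, Ptgds by -5.13 ± 0.35 and the lipid carrier gene Apod by -4.81 ± 0.38. Arrays of both groups were separated in each, with adjusted p at or below 5e-08. Of 11619 genes and unnamed probes, 7368 passed, 3848 higher and 3520 lower. The share that was higher was 52.2%, and 65% with median scaling, which moved the median of all genes from 0.05 to 0.28.

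In the ribosome-bound RNA of PTEN-deleted glioma, all 9 myelin genes fell relative to normal brain (median -3.90), with Mobp at -4.50 ± 0.78 and Trf, an iron carrier, at -4.10 ± 0.45. Of 7 astrocyte markers 6 fell (median -1.44), with Gja1 at -5.50 ± 0.22. All 3 neuron markers fell (median -1.42), with Gad1, of GABA synthesis, at -1.89 ± 0.21 and Eno2 at -1.42 ± 0.14. All 13 replication genes rose (median 3.02), with Mcm2 at 3.17 ± 0.27, and all 10 mitosis genes rose (median 3.52), with Plk1 at 4.46 ± 0.21 and Aurka at 3.54 ± 0.24. All 4 homologous recombination genes rose (median 2.01), with Rad54l at 3.24 ± 0.33. In the camera test the adjusted p was 1.7e-06, 0.00098, 0.0099, 9.2e-07, 3e-07 and 0.0086 in this order. With an estimated correlation the adjusted p was 0.18, 0.097, 0.18, 0.20, 0.19 and 0.20.

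Of 54 ribosomal protein genes 42 rose in this comparison (median 0.56), with Rplp0 at 2.56 ± 0.15. All 12 other terminal oligopyrimidine mRNAs rose (median 1.05), with Eef2 at 2.20 ± 0.24. Of 11 immediate early genes 6 rose and 1 fell (median 2.10), with Ier3 at 3.59 ± 0.25 and Jund at -1.36 ± 0.18. Among 9 FOXO target genes 6 fell, or 7 with 1 rising adjusted over the list alone (median -0.54), with Pik3ip1 at -2.51 ± 0.21. As lists, their camera adjusted p was 3e-07, 0.00033, 0.012 and 0.015 in this order, and with an estimated correlation the adjusted p was 0.18, 0.20, 0.30 and 0.20.

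Of 13 hypoxia and glycolysis genes 10 rose and 1 fell (median 1.16), with Hk2 at 3.01 ± 0.25. Of 8 interferon genes 7 rose (median 4.09), with Isg15 at 4.64 ± 0.39. Of 10 matrix and mesenchymal genes 8 rose, or 9 adjusted over the list alone, and 1 fell (median 2.24), with the galectin gene Lgals1 at 3.25 ± 0.16. Of 12 p53 target genes 9 rose and 1 fell (median 0.75), with Cdkn1a at 3.19 ± 0.16. The camera adjusted p was 0.0024, 0.0012, 0.0024 and 0.042 in this order, and with an estimated correlation the adjusted p was 0.36, 0.29, 0.20 and 0.20. The p53 call ended with the stricter filter (adjusted p = 0.055), without PTEN-deleted glioma replicate 3 (0.051) and without normal brain replicate 4 (0.053).

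Single genes that rose in the ribosome-bound RNA of PTEN-deleted glioma included Moxd1 at 5.78 ± 0.28, Tubb6 at 5.75 ± 0.14, Vim at 4.76 ± 0.20 and Chaf1b, a histone chaperone, at 4.39 ± 0.32. Those that fell included Cldn10 at -4.86 ± 0.27, the surface protein gene Thy1 at -4.49 ± 0.23 and Napb, of synaptic vesicle fusion, at -4.22 ± 0.23. Each was separated between the groups, with adjusted p at or below 1.9e-08. In this comparison 7079 of 11619 passed, 3618 higher and 3461 lower. The share that was higher was 51.1%, and 32.1% with median scaling, which moved the median of all genes from 0.04 to -0.21.

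Both gliomas shared 2609 rises and 2663 falls from normal brain in ribosome-bound RNA, where independent calls would give 1198 and 1049. A further 190 were called in opposite directions. The covariance of the differences was 1.23 (r = 0.88 across genes), against 0.02 (r = 0.5) in simulated data with shared controls, and 1.21 to 1.23 with the normal arrays split. Across the 11040 genes tested in both fractions, the change of PDGF glioma in ribosome-bound RNA correlated with that in total RNA with r = 0.79 and a covariance of 1.3. Both fractions come from the same tissue samples, and with group means removed the other 34 splits of these samples gave r of 0.20 to 0.59 and a covariance of at most 0.024. In both fractions 2672 genes rose and 2281 fell, where independent calls would give 1373 and 961, and 379 were called in opposite directions. For PTEN-deleted glioma r was 0.77 (0.07 to 0.50 in the other splits) and the covariance 1.2 (at most 0.03), with 2406 shared rises and 2133 shared falls, against 1222 and 930, and 421 opposite.

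Deletion of PTEN in the PDGF glioma was examined by comparing both gliomas directly. In total RNA, PTEN-deleted glioma had higher levels of some myelin, mitosis and lipid synthesis genes. Of 9 myelin genes 5 rose, or 6 adjusted over the list alone (median 0.77), with Opalin at 2.51 ± 0.51 and Mag at 2.26 ± 0.59, although these levels stayed below those of normal brain. Neither the astrocyte nor the neuron list passed. Of 7 astrocyte markers 1 rose, or 0 adjusted over the list alone (median 0, camera adjusted p = 0.98), and of 3 neuron markers 2 fell and 1 rose (median -0.94, camera adjusted p = 0.28). Syn1 changed by -1.24 ± 0.17 and Gad1 by -0.94 ± 0.21, and Gja1 by 1.54 ± 0.51 (adjusted p = 0.049), a call that ended in 11 other settings (adjusted p from 0.052 to 0.12). On the first principal component PTEN-deleted total RNA replicate 3 lay nearest normal brain of its group, at -24.1 against -47.6 to -37.3. Of 10 mitosis genes 6 rose, or 7 adjusted over the list alone (median 0.67), with Plk1 at 1.53 ± 0.21 and Aurka at 1.07 ± 0.23, the latter not called with median scaling (adjusted p = 0.11). Adjusted p by camera was 0.0094 and 0.0063, and with an estimated correlation it was an adjusted p of 0.95 for both. The myelin median was 0.18 with median scaling, 1.17 without PTEN-deleted glioma replicate 2, 0.37 without replicate 3 and 1.33 without PDGF glioma replicate 1, and the mitosis median was 0.10 with median scaling and 0.41 without PDGF glioma replicate 2. The replication list had 3 rises and 1 fall, or 6 and 1 adjusted over the list alone, with a median of 0.50 that became -0.02 with median scaling. Its camera adjusted p was 0.032, and 0.95 with an estimated correlation. The replication call ended with array weights (adjusted p = 0.13), without PDGF glioma replicate 2 (0.27, median 0.23) and without PTEN-deleted glioma replicate 1 (0.099) or 4 (0.079). Of 15 cholesterol and fatty acid synthesis genes 6 rose, or 7 adjusted over the list alone, with a median of 0.41 that became -0.14 with median scaling. Scd2, a fatty acid desaturase, rose by 1.41 ± 0.17, and the camera adjusted p of 0.0094 was an adjusted p of 0.95 with an estimated correlation, 0.057 with array weights and 0.051 without PDGF glioma replicate 1.

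Oxidative phosphorylation subunits had 11 rises and 4 falls among 68 genes, or 12 and 4 adjusted over the list alone, with a median of 0.13 in total RNA that became -0.37 with median scaling. By camera, the adjusted p was 0.047, and 0.95 with an estimated correlation. The call ended with the mean of a gene's probes (adjusted p = 0.053), with median scaling (0.68), without PDGF glioma replicate 3 (0.26) or 4 (0.076) and without PTEN-deleted glioma replicate 1 (0.099) or 3 (0.093). Of 9 FOXO target genes 3 fell and none rose (median -0.16, camera adjusted p = 0.22), with Txnip at -1.52 ± 0.27. None of the 13 hypoxia genes (median 0.36, camera adjusted p = 0.29) and none of the 8 interferon genes (median 0.28, camera adjusted p = 0.85) passed the threshold in total RNA. Without PDGF glioma replicate 2 the interferon list passed (adjusted p = 0.014, median 1.11), as did the p53 list (0.037, median 0.47, against 0.13 and 0.38 with all arrays). Without PTEN-deleted glioma replicate 3 the hypoxia list passed (0.027), and median scaling called the interferon (0.0088), hypoxia (0.029), p53 (0.0082) and homologous recombination lists (0.011), with medians of -0.29, -0.19, -0.09 and -0.06. The genes with the largest rises included the neuropeptide gene Npy at 2.16 ± 0.36, Enpp6, of differentiating oligodendrocytes, at 2.24 ± 0.25, and the cell cycle inhibitor gene Cdkn1c at 1.83 ± 0.25. Those with the largest falls included Dlk1 at -2.28 ± 0.35 (adjusted p = 0.1 with no background correction), Vgf at -2.27 ± 0.21, Socs2 at -1.79 ± 0.34 and the GTPase gene Rhob at -1.49 ± 0.14. Of 12212 tested, 2220 passed, 1074 higher and 1146 lower, or 48.4% higher. Median scaling gave 6304, of which 10% were higher, and moved the median of all genes from 0 to -0.39.

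In ribosome-bound RNA no list passed in the comparison of both gliomas as fitted, although some passed under other settings. Of 10 mitosis genes 6 rose, or 7 adjusted over the list alone (median 0.71, camera adjusted p = 0.067), with Plk1 at 1.71 ± 0.21. Of 13 hypoxia and glycolysis genes 7 rose (median 0.36, camera adjusted p = 0.24), with the glucose transporter gene Slc2a1 at 1.28 ± 0.27 and Hk2 at 1.28 ± 0.25 (adjusted p = 0.083 for Hk2 with median scaling). Among 9 FOXO target genes 4 fell (median -0.27, camera adjusted p = 0.31), with Txnip at -1.47 ± 0.26. Pdgfra changed by -1.02 ± 0.17 and Egfr by 1.02 ± 0.23 (adjusted p = 0.00033 and 0.0032), the latter not called with median scaling (0.14). Single genes that rose included Cdkn1c at 2.19 ± 0.25, Ddit4l, an inhibitor of mTOR signalling, at 2.18 ± 0.23 and Gtse1, of the G2 and S phases, at 1.75 ± 0.23. Those that fell included the chaperonin gene Cct5 at -2.71 ± 0.21, Rhob at -2.51 ± 0.14, the lipid carrier gene Fabp7 at -2.40 ± 0.26 and Pcna at -2.30 ± 0.27. Of 11619 tested, 4037 passed, 2029 higher and 2008 lower, or 50.3% higher. Median scaling gave 6844, of which 11.5% were higher and moved the median of all genes from 0 to -0.46. It called 7 lists: ribosomal protein (adjusted p = 1.1e-05), mitosis (3.8e-05), myelin (0.0013), homologous recombination (0.002), hypoxia (0.0085), replication (0.011) and matrix genes (0.011). Their medians were -0.13, 0.24, 0.01, 0.14, -0.14, -0.13 and -0.10 in this order, each above that of all genes, and 4 of them were below 0. The mitosis list also passed with array weights (0.031), the replicate block (0.043), the mean of a gene's probes (0.05 when rounded) and without PDGF glioma replicate 1 (0.046) or 3 (0.0032). Without replicate 1 the myelin list passed (0.046, median 0.92 rather than 0.39), and without replicate 3 the replication (0.025, median 0.75 rather than 0.45) and homologous recombination lists (0.025). Across 11040 genes the changes in both fractions correlated with r = 0.79 and a covariance of 0.2, against r of 0.20 to 0.58 and a covariance of at most 0.05 in the other splits with group means removed. Of the calls, 841 were higher and 866 lower in both, where independent calls would give 188 of each, and 0 were opposite.

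Ribosome-bound RNA was then compared with total RNA of the same tissue samples, a paired comparison in which the fractions also differ in how they were isolated. In normal brain, ribosome-bound RNA had higher levels of neuron, oxidative phosphorylation and ribosomal protein genes than total RNA. All 3 neuron markers were higher (median 1.59), with Eno2 at 1.64 ± 0.12 and Syn1, of synaptic vesicles, at 1.59 ± 0.11 (n = 4 pairs). Of 68 oxidative phosphorylation genes 59 were higher and 4 lower (median 0.79), with Ndufc1 at 1.43 ± 0.08 and Uqcrc2 at -1.13 ± 0.08. Among 54 ribosomal protein genes 51 were higher and none lower by the probe counted (median 0.57), with Rpl22 at 1.72 ± 0.10. Rpl23 had probes called in opposite directions in all 3 tissues. These lists had camera adjusted p of 0.049, 1.4e-08 and 1.4e-08, and with an estimated correlation the adjusted p was 0.32 for each. The neuron call ended with no background correction (adjusted p = 0.05), median scaling (0.068), fractions normalized separately (0.061), the mean of a gene's probes (0.051) and without normal brain replicate 3 (0.05). It also ended with no replicate block, that is, unpaired (0.067).

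Lower in the ribosome-bound RNA of normal brain were 12 of 13 replication genes (median -1.21), with Uhrf1 at -2.01 ± 0.14, and 9 of 10 mitosis genes (median -1.01), with Top2a at -2.04 ± 0.22. Of 15 cholesterol and fatty acid synthesis genes 14 were lower and 1 higher (median -1.29), with Acaca, of fatty acid synthesis, at -2.15 ± 0.13. Of 9 FOXO target genes 7 were lower and 1 higher (median -1.13), with Txnip at -1.87 ± 0.17. In the camera test the adjusted p was 8e-05, 0.0022, 2.8e-05 and 0.013 in this order, and with an estimated correlation the adjusted p was 0.32, 0.33, 0.21 and 0.21. Single genes with the largest positive differences included the GTPase gene Rit2 at 5 ± 0.29, the calcium binding protein genes Calb2 at 4.71 ± 0.17 and Vsnl1 at 4.59 ± 0.17, and Resp18, of peptide secretion, at 4.65 ± 0.17. The largest negative differences included Erich5 at -5.43 ± 0.30, Wsb1 at -4.66 ± 0.18 and the cytolinker gene Dst at -3.58 ± 0.18. All 4 pairs showed the direction in each gene, with adjusted p at or below 6e-11. The paired fit called 8321 of 13145, 4002 higher and 4319 lower, or 48.1% higher, and 59.4% with median scaling.

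In both gliomas, ribosome-bound RNA had higher levels of oxidative phosphorylation and ribosomal protein genes than paired total RNA and lower levels of immediate early genes. In PDGF glioma 60 of 68 oxidative phosphorylation genes were higher and 2 lower (median 0.73), with Ndufb4 at 3.02 ± 0.16 and Atp5e at 2.78 ± 0.14. In PTEN-deleted glioma 55 were higher, or 57 adjusted over the list alone, and 2 lower (median 0.67), with Atp5e at 2.20 ± 0.14. Of 54 ribosomal protein genes 29 were higher in PDGF glioma, or 30 adjusted over the list alone, and 4 lower (median 0.25), and 34 in PTEN-deleted glioma, or 36 adjusted over the list alone, with 2 lower (median 0.33). Against genes of like genomic length the ribosomal protein median turned negative, to -0.29 in PDGF glioma (95% interval -0.35 to -0.16) and -0.25 in PTEN-deleted glioma (-0.35 to -0.15), and in normal brain it was 0.07. Of 11 immediate early genes 9 were lower and 1 higher in PDGF glioma (median -0.76), with Klf6 at -1.62 ± 0.10 and Fos at -1.22 ± 0.13, and 8 lower and none higher in PTEN-deleted glioma (median -0.90), with Klf6 at -2.19 ± 0.10 and Dusp1 at -1.25 ± 0.17. The camera adjusted p in PDGF glioma was 5.7e-12 for oxidative phosphorylation, 0.023 for ribosomal proteins and 0.021 for immediate early genes, and with an estimated correlation the adjusted p was 0.60, 0.72 and 0.60. In PTEN-deleted glioma it was 2.9e-10, 0.00086 and 0.0038, and with an estimated correlation the adjusted p was 0.50, 0.65 and 0.50. In PDGF glioma the immediate early call ended with fractions normalized separately (adjusted p = 0.051), without replicate 2 (0.051) and with no replicate block (0.13), and the ribosomal protein call without replicate 2 (0.071). The cholesterol list was also lower in PTEN-deleted glioma, with 9 of 15 genes lower, or 10 adjusted over the list alone, and 1 higher (median -0.73, camera adjusted p = 0.012, adjusted p = 0.50 with an estimated correlation).

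**Figure D2:**
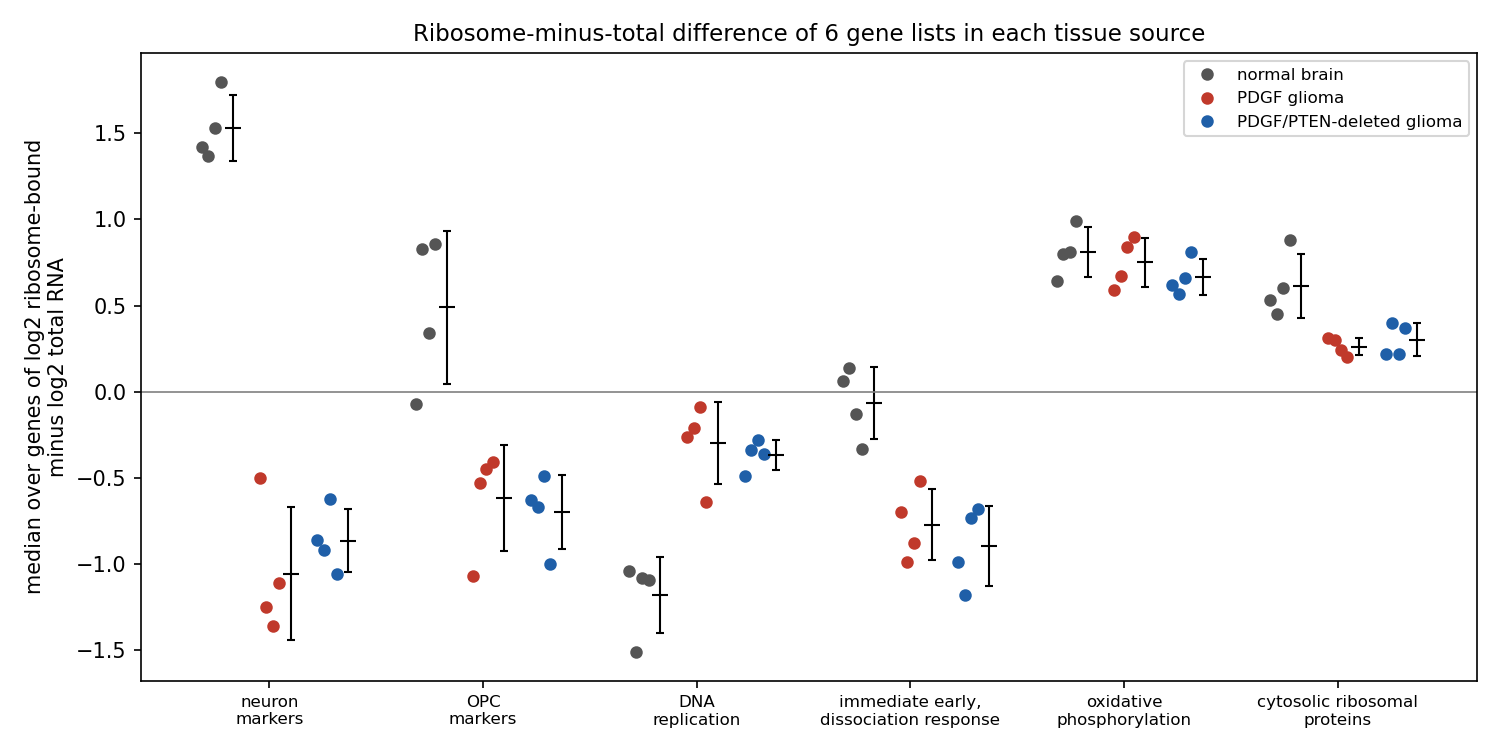
Median log2 ribosome-bound minus total RNA of 6 gene lists in each of the 12 tissue samples, by tissue; points are tissue samples and bars the mean ± SD of 4. Neuron markers lay between 1.37 and 1.80 in normal brain, between -1.36 and -0.50 in PDGF glioma and between -1.06 and -0.62 in PTEN-deleted glioma.

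Of 3 neuron markers 2 were lower in the ribosome-bound RNA of PDGF glioma (median -1.12, camera adjusted p = 0.21) and 2 in PTEN-deleted glioma (median -0.86, camera adjusted p = 0.25). Some single genes had large differences in both gliomas. Gipc1, a scaffold of membrane receptors, had a paired difference of 3.96 ± 0.21 in PDGF glioma and 3.44 ± 0.21 in PTEN-deleted glioma. Erich5 was at -4.92 ± 0.30 and -4.25 ± 0.30, the glutamate receptor gene Gria2 at -3.60 ± 0.29 and -3.85 ± 0.29, and the transferrin receptor gene Tfrc at -3.12 ± 0.17 and -2.93 ± 0.17. Gfap was at 2.14 ± 0.25 and 2.29 ± 0.25. All 4 pairs showed the direction in each of these, with adjusted p at or below 1e-06. The paired fit called 7463 of 13145 in PDGF glioma, 3693 higher and 3770 lower, and 7501 in PTEN-deleted glioma, 3691 higher and 3810 lower. Across genes, the ribosome-minus-total differences of both gliomas correlated with r = 0.89, and those of normal brain with PDGF and PTEN-deleted glioma with r = 0.56 and 0.57. The differences followed genomic length in every tissue. Spearman's correlation with length was -0.24 in normal brain, -0.39 in PDGF glioma and -0.42 in PTEN-deleted glioma across 6968 genes.

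**Figure D3:**
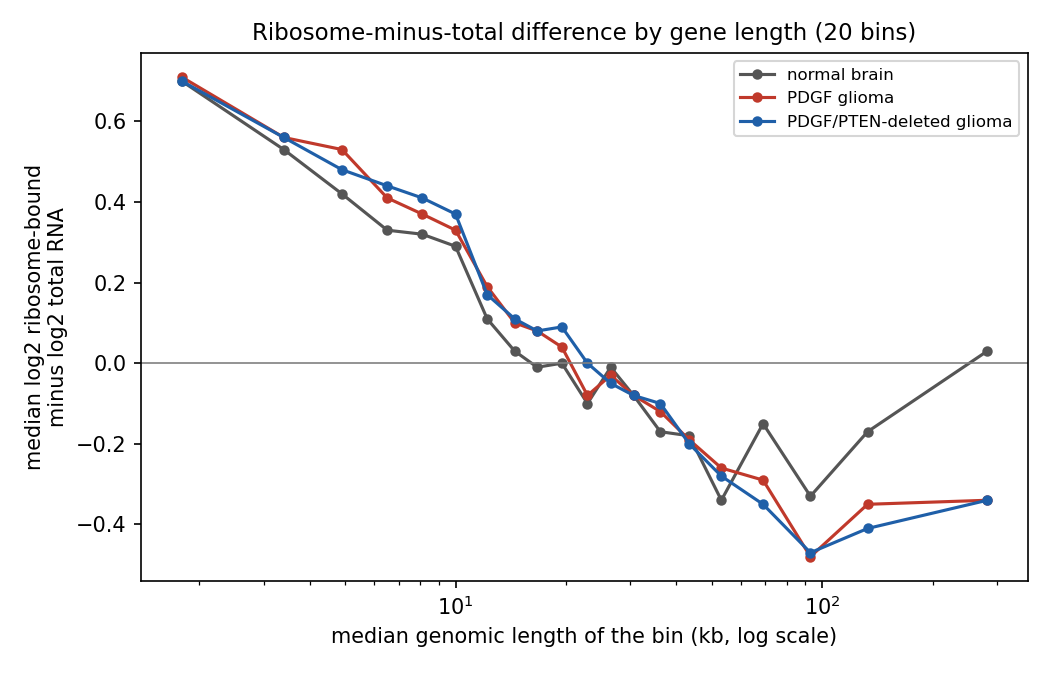
Median log2 ribosome-bound minus total RNA of named genes in 20 bins of genomic length (kb, log scale), for each tissue. The shortest bin (median 1.79 kb) lay at 0.70 to 0.71 in the 3 tissues, and the longest (282 kb) at 0.03 in normal brain and -0.34 in both gliomas.

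The question of the series title was approached by testing whether the paired ribosome-minus-total difference itself changed between tissues, as an interaction of tissue and fraction. The fractions differ in isolation, so effects of sorting or dissociation that differ by tissue also enter this change. It is not a measure of translation alone. Relative to normal brain, the difference fell in PDGF glioma for neuron, oligodendrocyte progenitor, immediate early and ribosomal protein genes and rose for cell cycle and cholesterol synthesis genes. All 3 neuron markers fell (median -2.28), with Eno2 at -2.83 ± 0.17 and Gad1 at -2.28 ± 0.21. In normal brain these markers had been higher in ribosome-bound than in total RNA. Of 12 oligodendrocyte progenitor markers 9 fell (median -1.48), with Cacng4 at -2.95 ± 0.22 and Gpr17 at -1.82 ± 0.25. Of 11 immediate early genes 7 fell (median -0.72), with Egr2 at -1.63 ± 0.22 and Ier3 at -1.54 ± 0.19. Among 54 ribosomal protein genes 29 fell, or 33 adjusted over the list alone (median -0.38), with Rps15a at -1.77 ± 0.20. As lists, their camera adjusted p was 0.00071, 0.00071, 0.0032 and 4.4e-06 in this order, and with an estimated correlation the adjusted p was 0.14, 0.28, 0.24 and 0.32.

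For 11 of 13 replication genes the paired difference rose in PDGF glioma (median 1.25), with Pcna at 2.13 ± 0.19 and Rrm2 at 1.92 ± 0.26, and for 9 of 10 mitosis genes (median 0.91), with Cdk1 at 1.06 ± 0.17. Of 15 cholesterol and fatty acid synthesis genes 11 rose, or 12 adjusted over the list alone, and 1 fell (median 0.83), with Fdps, of isoprenoid synthesis, at 1.61 ± 0.12. Among 9 FOXO target genes 5 rose (median 0.65), with Txnip at 1.80 ± 0.24, and of 7 astrocyte markers 5 rose and 1 fell (median 1.11), with Gja1 at 2.02 ± 0.37. The camera adjusted p was 0.00014, 0.00071, 0.00027, 0.036 and 0.045 in this order, and with an estimated correlation the adjusted p was 0.28, 0.28, 0.24, 0.24 and 0.32. The astrocyte call ended with no background correction (adjusted p = 0.064), fractions normalized separately (0.067), the authors' values (0.057), no replicate block (0.14), and without PDGF glioma replicate 2 (0.064) or normal brain replicate 1 (0.073) or 4 (0.065). The FOXO call ended with no background correction (0.064), fractions normalized separately (0.058), the authors' values (0.14), no replicate block (0.077), and without PDGF glioma replicate 4 (0.063) or normal brain replicate 4 (0.065).

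Single genes whose paired difference fell in PDGF glioma included Vgf, by at least 23.3-fold, since it was not above background in normal total RNA. Syt4, of vesicle trafficking, changed by -4.83 ± 0.29, the creatine kinase gene Ckmt1 by -4.70 ± 0.16 and Rbfox1, a neuronal splicing factor, by -4.06 ± 0.19. The cyclin gene Ccnd1 changed by -3.32 ± 0.23. Rises included Acta2, a smooth muscle actin and a pericyte marker, at 3.61 ± 0.28, the histone gene H3c1 at 3.25 ± 0.29, Cdca7 at 3.12 ± 0.21 and Egfr at 2.31 ± 0.22. Every tissue sample of one tissue lay on the same side of every sample of the other in each, with adjusted p at or below 2.4e-07. Of 13145 genes and unnamed probes 5321 passed, 2764 higher and 2557 lower. The share that was higher was 51.9%, and 37.4% with median scaling, which moved the median of all genes from 0.05 to -0.09.

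In PTEN-deleted glioma the paired difference fell from normal brain for neuron, oligodendrocyte progenitor, immediate early and ribosomal protein genes and rose for cell cycle and cholesterol synthesis genes. All 3 neuron markers fell (median -2.29), with Eno2 at -2.50 ± 0.17. Of 12 oligodendrocyte progenitor markers 10 fell (median -1.46), with Cacng4 at -3.38 ± 0.22 and Pdgfra at -1.81 ± 0.27. Of 11 immediate early genes 8 fell, or 9 adjusted over the list alone (median -0.89), with Klf6 at -1.50 ± 0.14. Of 54 ribosomal protein genes 27 fell and 1 rose, or 30 and 1 adjusted over the list alone (median -0.33), with Rps15a at -2.34 ± 0.20, and with median scaling the list's test was reversed and not past the threshold (median -0.07, adjusted p = 0.22). Adjusted p by camera was 0.00095, 0.00053, 0.00069 and 0.00036 in this order, and with an estimated correlation the adjusted p was 0.16, 0.30, 0.20 and 0.44.

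Replication genes rose in 10 of 13 cases, or 11 adjusted over the list alone (median 1.08), with Cdc45 at 1.41 ± 0.24, and mitosis genes in 9 of 10 (median 0.87), with Cdk1 at 1.32 ± 0.17. Of 15 cholesterol and fatty acid synthesis genes 9 rose, or 10 adjusted over the list alone, and 1 fell (median 0.58), with Fdps at 1.46 ± 0.12. Of 9 FOXO target genes 5 rose (median 0.61), with Txnip at 1.86 ± 0.24. The camera adjusted p of these paired differences was 0.00053, 0.0011, 0.0041 and 0.025 in this order, and with an estimated correlation the adjusted p was 0.30, 0.30, 0.30 and 0.20. The FOXO call ended with the authors' values (adjusted p = 0.19), with no replicate block (0.064) and without normal brain replicate 4 (0.051). Single genes included Ckmt1 at -4.90 ± 0.16, Syt4 at -4.41 ± 0.29, Rbfox1 at -4.34 ± 0.19, Acta2 at 3.76 ± 0.28, Egfr at 3.22 ± 0.22 and H3c1 at 3.18 ± 0.29, all separated between the tissues with adjusted p at or below 1.2e-07. Vgf fell by at least 12.4-fold. Of 13145, 5352 passed, 2749 higher and 2603 lower, or 51.4% higher, and 27.4% with median scaling, which moved the median of all genes from 0.06 to -0.15.

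Both gliomas shared 1961 rises and 2114 falls of this difference, where independent calls would give 578 and 506, and 5 were opposite. The covariance was 0.68 (r = 0.91 across genes), against 0.027 (r = 0.5) in simulated data with shared controls, and 0.65 to 0.66 with the normal tissue samples split between the comparisons.

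Between the gliomas the paired difference changed for 363 of 13145 genes and unnamed probes, 70 higher and 293 lower in PTEN-deleted glioma. Genes that fell included Gja1 at -1.92 ± 0.37, Cct5 at -1.71 ± 0.23, the amino acid transporter gene Slc3a2 at -1.51 ± 0.21 and Pcna at -1.50 ± 0.19. Genes that rose included the lysosomal enzyme gene Idua at 1.24 ± 0.25, Egfr at 0.92 ± 0.22 and the receptor kinase gene Axl at 0.86 ± 0.17. With no replicate block the calls of Gja1 (adjusted p = 0.12), Egfr (0.14) and Axl (0.48) ended. Those of Egfr (0.13) and Axl (0.051) also ended with median scaling, Axl with a random block (0.21), and Egfr with no background correction (0.11), no filter (0.075), without PTEN-deleted glioma replicate 1 (0.084), 3 (0.059) or 4 (0.1) and without PDGF glioma replicate 2 (0.061), 3 (0.1) or 4 (0.077). Of 68 oxidative phosphorylation genes 8 fell, or 11 adjusted over the list alone (median -0.06, which became 0.07 with median scaling), with Ndufb4 at -1.38 ± 0.23 and Sdhd at -1.14 ± 0.17. Of 15 cholesterol genes 1 fell, or 2 adjusted over the list alone (median -0.15), and of 7 astrocyte markers 2 fell (median -0.30). None of the 9 myelin genes (median -0.56) passed on its own, nor did the 10 matrix genes (median 0.38), of which 1 rose when adjusted over the list alone. By camera, the adjusted p was 0.0071 for oxidative phosphorylation, 0.025 for cholesterol and for myelin, and 0.037 for astrocyte and for matrix genes, and with an estimated correlation the adjusted p was 0.61 for each.

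Each of these list calls between the gliomas ended under some setting, and the medians moved with single tissue samples. The myelin median was -0.12 without PTEN-deleted glioma replicate 3, -0.20 without PDGF glioma replicate 4, -0.23 with array weights and -0.85 to -0.91 without PTEN-deleted glioma replicate 1 or 2 or PDGF glioma replicate 3. The astrocyte median was -0.19 and the matrix median 0.25 without PTEN-deleted glioma replicate 4. The cholesterol median was -0.08 without PDGF glioma replicate 3, -0.25 without replicate 4 and -0.28 with median scaling. The oxidative phosphorylation median was -0.10 without PTEN-deleted glioma replicate 4, -0.11 without PDGF glioma replicate 1 and -0.01 without replicate 3. The myelin call ended without PTEN-deleted glioma replicate 3 (adjusted p = 0.57) or 4 (0.058), without PDGF glioma replicate 4 (0.51), with no replicate block (0.079), median scaling (0.15), array weights (0.36), the authors' values (0.056) and the mean of a gene's probes (0.055). The astrocyte call ended without PTEN-deleted glioma replicate 3 (0.095) or 4 (0.083), without PDGF glioma replicate 2 (0.057) or 3 (0.084), with no replicate block (0.15), array weights (0.11), the authors' values (0.056) and the mean of a gene's probes (0.077). The matrix call ended without PTEN-deleted glioma replicate 3 (0.13) or 4 (0.058), without PDGF glioma replicate 1 (0.068) or 4 (0.23), with no replicate block (0.15), array weights (0.23) and the authors' values (0.056). The cholesterol call ended without PTEN-deleted glioma replicate 4 (0.058) or PDGF glioma replicate 3 (0.084) and with the mean of a gene's probes (0.055). The oxidative phosphorylation call ended without PDGF glioma replicate 4 (0.091) and with median scaling (0.24). Other lists gained a call. Without PDGF glioma replicate 2 these were the immediate early (0.032), homologous recombination (0.032), ribosomal protein (0.025) and interferon lists (0.0053). The ribosomal protein list also passed with median scaling (2.3e-19), the mean of a gene's probes (0.03), no replicate block (0.044) and without PDGF glioma replicate 1 (0.036) or PTEN-deleted glioma replicate 1 (0.013) or 3 (0.027), the interferon list without PDGF glioma replicate 1 (0.031) or PTEN-deleted glioma replicate 1 (0.026), the hypoxia list with median scaling (0.038) and the replication list without PDGF glioma replicate 4 (0.035). The count of 363 became 220 with no replicate block, 240 without PTEN-deleted glioma replicate 4, 140 with no background correction, 186 of 7494 with the authors' values and 815 with median scaling.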

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

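The tests of normalization for the oxidative phosphorylation and immediate early patterns, of isolation method and of gene length for the ribosomal protein genes were chosen only after the result was seen. The second gene lists used here were written after these patterns were seen and before their own values were.

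Neuron genes were higher in ribosome-bound than in total RNA of normal brain, and not in the gliomas. Of 69 genes written for a second neuron list 33 could be used, none of them in the lists above and all above background in both gliomas. This list lay 1.33 above all genes in normal brain (95% interval 0.81 to 2.04, 23 higher and 7 lower), against 0.09 in PDGF and -0.09 in PTEN-deleted glioma. Naming required a level above background in ribosome-bound but not in total RNA of normal brain, which favours this direction. Genes above background in every glioma array also need not be specific to neurons. Among the most abundant genes of the list, Rtn1 had levels of 13.57 ± 0.11 in ribosome-bound and 11.91 ± 0.15 in total RNA of normal brain and Cplx1 13.17 ± 0.12 and 9.79 ± 0.17, but Syt11 14.69 ± 0.17 and 15.12 ± 0.11 (mean ± SD, n = 4). Relative to all genes, the list lay at 1.34 or more over 3 other normalizations, but the neuron marker call ended with each. RNA of neurons in the immunoprecipitate, which the GFP sort would remove from total RNA, is a candidate with the values it needs. RNA of every unsorted cell type cannot be told apart (0.13 for 18 blood vessel and microglia genes, interval -0.45 to 0.91). Nor can ribosome loading that differs by tissue (1.24 between normal brain and PDGF glioma).

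Oxidative phosphorylation and ribosomal protein genes were higher in ribosome-bound RNA of every tissue. Other normalizations left the oxidative phosphorylation list 0.60 to 1.14 above all genes, so its size depended on them. Against genes of like genomic length, the ribosomal protein list lay at 0.07 in normal brain, -0.29 in PDGF and -0.25 in PTEN-deleted glioma, from 0.50, 0.20 and 0.26, so a trend with length may account for its rise. The oxidative phosphorylation list kept 0.54, 0.37 and 0.29 of 0.72, 0.68 and 0.60 (intervals 0.28 to 0.65, 0.30 to 0.49 and 0.15 to 0.41), so genomic length did not account for all of it, but it only approximates transcript length and the rest cannot be told apart from such a trend. The isolation of the fractions cannot be told apart from ribosome binding either, since it differs in the same way in all 3 tissues.

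Immediate early genes were lower in ribosome-bound than in total RNA of both gliomas. A trend with length is argued against, since the list lay at -1.36 or lower against genes of like length. Relative to all genes it was -0.76 or lower over 3 other normalizations. A response to dissociation in the sorted cells, which only the total RNA would carry, might contribute. A second list of 23 dissociation response genes lay at -0.46 in normal brain (interval -0.90 to -0.20), -0.45 in PTEN-deleted and -0.11 in PDGF glioma, while the immediate early list itself lay at -0.13 in normal brain, so this cannot be told apart from a difference between the tissues, which was not tested further.

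Ribosome-minus-total differences differed between tissues by the interaction test in 5321 (PDGF glioma against normal brain), 5352 (PTEN-deleted glioma against normal brain) and 363 genes and unnamed probes (between the gliomas). This test does not separate ribosome binding from isolation effects that differ by tissue. For the first and second counts the highest over the other 34 splits of the 8 tissue samples was 0. Mixed splits carry the tissue difference as spread, which lowers their counts, so this alone does not exclude chance. For the third another split gave 248, or 68.3% of the real count, and 240 were called without PTEN-deleted glioma replicate 4, so although no other split gave as many (share 0.029, the smallest possible), the count between the gliomas is weaker evidence. In PDGF glioma against normal brain the list medians that differed were -1.48 for oligodendrocyte progenitor, -2.28 for neuron, 1.11 for astrocyte, -0.72 for immediate early, 1.25 for replication, 0.91 for mitosis, -0.38 for ribosomal protein, 0.65 for FOXO target and 0.83 for cholesterol genes. In PTEN-deleted glioma they were -1.46, -2.29, -0.89, 1.08, 0.87, -0.33, 0.61 and 0.58 in this order without astrocyte genes. Of these, the astrocyte and FOXO calls in PDGF glioma ended with no replicate block (adjusted p = 0.14 and 0.077) and the authors' values (0.057 and 0.14), the FOXO call in PTEN-deleted glioma ended with the authors' values (0.19), and its ribosomal protein test reversed with median scaling (median -0.07, adjusted p = 0.22). Between the gliomas they were -0.56 for myelin, -0.30 for astrocyte, -0.06 for oxidative phosphorylation, -0.15 for cholesterol and 0.38 for matrix genes, but none of these 5 was called in every setting, and without 1 tissue sample they reached -0.12, -0.19, -0.01, -0.08 and 0.25.

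In each of the 6 comparisons of tissues within a fraction, 1 of 35 splits, the real one, gave a count as large. For the same reason these splits alone do not exclude chance. In total RNA the real counts were 7985, 7642 and 2220 and the highest others 0, 0 and 38, for PDGF glioma, PTEN-deleted glioma and the comparison of both. In ribosome-bound RNA the real counts were 7368, 7079 and 4037, and the highest others 0%, 0% and 4.16% of these. Within a tissue the 8 splits of 4 pairs were too few for a share under 0.05, with real counts of 8321, 7463 and 7501 and highest others of 0, 1 and 0 in normal brain, PDGF glioma and PTEN-deleted glioma.

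Of 150 groups of 4 values tested for a sample far from the others, 9 had one, where chance gives about 5%. In ribosome-bound RNA of PDGF glioma, replicate 1 had a mean level of 12.19 for terminal oligopyrimidine mRNAs (others 11.87 to 11.89) and replicate 4 of 9.15 for matrix genes (others 9.68 to 9.70). In its total RNA, replicate 2 had 9.32 for mitosis genes (others 10.35 to 10.55) and 11.29 for hypoxia genes (others 10.87 to 10.91). In PTEN-deleted glioma, the neural progenitor list had 8.64 in ribosome-bound replicate 1 (others 8.75 to 8.76) and 9.05 in total RNA replicate 2 (others 8.87 to 8.90), and Egfr had 5.73 in total RNA replicate 1 (others 6.18 to 6.27). In normal brain, astrocyte markers had 10.68 in ribosome-bound replicate 1 (others 10.99 to 11) and Olig2 had 6.54 in total RNA replicate 4 (others 6.85 to 6.91).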

How the results depend on the processing

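All alternatives in this part were planned. Some counts of called genes moved by more than 1.5 times. With the authors' values, which hold fewer probes (7494 tested), counts were 5122 and 5085 for PDGF and PTEN-deleted glioma against normal brain in total RNA, 4648 and 4502 in ribosome-bound RNA, and 3397, 3506 and 186 for the change of the ribosome-minus-total difference in PDGF glioma, in PTEN-deleted glioma and between the gliomas. With median scaling they were 6304 in total RNA and 6844 in ribosome-bound RNA between the gliomas, and 815 for the ribosome-minus-total difference. The last count was also 140 with no background correction, 220 with no replicate block, and 240 to 313 with 1 tissue sample left out. Apart from the smaller table, the cause was not tested. With median scaling, 3 list tests reversed: ribosomal proteins (median -0.07, adjusted p = 0.22) and oxidative phosphorylation (-0.06, 0.016) in the ribosome-minus-total difference of PTEN-deleted glioma against normal brain, and oxidative phosphorylation (0.07, 0.24) in that between the gliomas; the cause was not tested. Of 4080 list results under alternatives 3947 kept their direction and side of the threshold, 75 lost the threshold and 55 gained it. Median scaling also moved called medians by over 1.5 times with no loss of the call, among them cholesterol genes from -1.02 to -0.33 in total RNA of PDGF glioma against normal brain, and ribosomal proteins from 0.57 to 1.03, 0.25 to 0.66 and 0.33 to 0.95 between the fractions of normal brain, PDGF and PTEN-deleted glioma. Of 4713 results of named genes 4674 kept both, 39 lost the threshold and 0 reversed. With the replicate number as a block, 7999 rather than 7985 genes were called in total RNA of PDGF glioma against normal brain. Without 1 replicate, counts ranged from 7467 to 7798 there, 7111 to 7481 for PTEN-deleted glioma and 1606 to 2079 between the gliomas, from 6789 to 7331, 6472 to 6846 and 3616 to 4018 in ribosome-bound RNA, from 7605 to 7810, 6639 to 7050 and 6562 to 7109 between the fractions of normal brain, PDGF and PTEN-deleted glioma, and from 4649 to 5168 and 4602 to 5058 for the change of that difference in PDGF and PTEN-deleted glioma. The array slide was not run as a block, since the files do not name it. Signal near background limits what can be seen: genes not above background have folds as bounds only.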

Other observations

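The tests of this part were not chosen after a result was seen, except that the values of PDGF glioma replicate 2 were singled out after they were seen.

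The lists that did not pass in total RNA of PDGF glioma against normal brain also held genes that did. The 23 translation initiation factors had a median of 0.47, with Eif1a at 2.56 ± 0.15 and Eif2b2 at -0.69 ± 0.14, which was -0.03 with median scaling (adjusted p = 0.88). Of 13 unfolded protein and integrated stress response genes 7 rose and 4 fell (median 0.48, camera adjusted p = 0.71). Asns, of asparagine synthesis, rose by 2.93 ± 0.19 and Chac1 by 2.60 ± 0.29, both targets of the integrated stress response, while Ddit3 changed by -1.59 ± 0.28 and the chaperone gene Dnajb9 by -1.24 ± 0.14. Of 13 neural progenitor and proneural glioma genes 3 rose and 5 fell (median -0.09, camera adjusted p = 0.31). Ccnd1 rose by 4.62 ± 0.26 and Ccnd2 by 2.04 ± 0.32, and the Notch target Hes5 changed by -2.65 ± 0.19 and Id3 by -2.01 ± 0.18. Of 68 oxidative phosphorylation subunits 15 rose and 24 fell (median -0.08, camera adjusted p = 0.1). That list was called with array weights (median -0.14, adjusted p = 0.033) and without PDGF glioma replicate 1 (median -0.16, adjusted p = 0.038). Of 4 homologous recombination genes 3 rose, or 4 adjusted over the list alone (median 1.05, camera adjusted p = 0.18), with Rad54l at 1.43 ± 0.31.

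Lists with too few members to test held C1qc, a microglial complement gene, at 1.71 ± 0.39, the pericyte actin gene Acta2 at -2.58 ± 0.44 with the endothelial gene Esam at -1.19 ± 0.42, and the ciliary gene Foxj1, above background on 3 of 4 normal arrays, at 0.74 ± 0.15 in the same comparison. Foxj1 was not called with the authors' values (adjusted p = 0.079). Esam was not called with median scaling (0.13), with all 24 arrays and a random block (0.052), without PDGF glioma replicate 2 (0.062) or 3 (0.056), or without normal brain replicate 4 (0.072). Erythrocyte genes and nuclear noncoding RNAs had 0 measured members, and sex-linked genes had 1.

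Tissue sample 2 of PDGF glioma had the lowest replication and highest interferon level of its group in both fractions, although neither passed the test for a sample far from the others. Its mean level of replication genes was 9.31 in total and 9.24 in ribosome-bound RNA, against 10.18 to 10.50 and 9.99 to 10.67 in the other replicates. Its mean level of interferon genes was 11.88 and 12.23, against 8.78 to 9.62 and 9.86 to 10.68. Without it, the interferon and p53 lists passed in total RNA between the gliomas (medians 1.11 and 0.47, adjusted p = 0.014 and 0.037), and the immediate early, homologous recombination, ribosomal protein and interferon lists gained a call in the paired ribosome-minus-total difference between them (adjusted p = 0.032, 0.032, 0.025 and 0.0053).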
